A study of Homo sapiens with 2 samples.

How the data were processed

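Total RNA of 2 THP-1 cultures was extracted with Trizol and sequenced as standard Illumina libraries, per the labels' protocols; strandedness and poly(A) selection are not given in the sources used here. The groups were taken from the treatment label: 1 library with DMSO and 1 with 2 µM OPA1, both for 48 h. The deposited table gives FPKM (fragments scaled to the length of the transcript and to the total of the library) per transcript, per the file headers. The submitters' processing notes name HISAT, StringTie, edgeR and the genome build hg19, without versions or roles, and coordinates below are those of the table. All 29373 rows were of type protein_coding and each reached at least 0.5 FPKM in 1 of the libraries, which was tested on the table, so transcripts of other types or below that level are not analysed here. A further 2 lines of the table were empty in the copy used and are not reported here. The authors' normalization sets each value relative to the reads of its library, so values show relative and not absolute amounts.

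Read depth is unknown. A search for the step that 1 read would give, in the 300 lowest genes with 1 listed transcript, found no step stronger than in jittered values (alignment 0.14 against at most 0.19 in the DMSO library and 0.12 against at most 0.20 in the OPA1 library), so counts were not recovered and no count test was run. With 1 library per group no test was possible, and an exact 0 may be a failed estimate of a transcript and not absence: 1337 transcripts were at 0 with DMSO and 1581 with OPA1.

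Transcripts were summed per gene symbol (3 symbols joined more than 1 gene ID). Genes with a mean of at least 1 FPKM over both libraries were kept, and the log2 ratio of OPA1 over DMSO was taken after adding 1 FPKM. All choices in this paragraph were made before the data were examined. Genes and transcripts were counted by size, at 2-fold. For 35 gene lists on opioid signalling, DNA methylation, proliferation, death, metabolism, stress, myeloid identity, immunity, library quality and other cell types, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of matched level. A list was said to stand apart below percentile 2.5 or above 97.5; the 4 lists of other cell types had fewer than 5 measured genes and got no percentile. Random lists treat genes as independent, so these percentiles describe the 2 libraries and are no test between treatments. List symbols were matched directly or through older symbols by gene ID, with 11613 of 11700 gene IDs in the name table. Named genes were the 15 highest and 15 lowest ratios without uncharacterised or small RNA symbols, up to 4 members of each list with the largest ratios in either direction, the listed opioid receptor, TET and DNMT genes, and the 5 largest exchanges between transcripts of 1 gene with a mean of at least 5 FPKM. Some genes picked by this rule or measured in the lists drawn are not reported here, though they count in the totals and medians.

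Alternatives were a pseudocount of 0.1 FPKM, a minimum mean of 5 FPKM or none, rescaling each library to a sum of 1000000, centring on the median gene, scaling on a mean trimmed by 30% at each end, the most abundant transcript of each gene in place of the sum, and the mean of a list in place of its median. The authors' own comparison statistics were not analysed here. Chosen after seeing the data were a restriction to genes with 1 annotated transcript, the removal of genes with opposing transcripts, a restriction to genes with steady transcript shares (at most 10% of a gene's FPKM on another listed transcript in the other library), and a fit on GC content, transcript length and level. Annotated transcripts, GC and length came from GENCODE release 29 by transcript and gene ID only, since that release is on another build; 29240 of the 29373 transcripts had a length. The list procedure was tested on simulated data for this comparison with 10601 genes: all 100 simulated lists of 20 genes shifted by 0.5 and all 100 shifted by -0.5 (log2) were placed outside the limits on the right side, and of 100 unchanged lists 2 lay above and 2 below. These shifts were larger in size than every list median reported below, and the simulated genes varied independently with normal noise. How the procedure places smaller shifts or lists of co-regulated genes was therefore not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.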

Results

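Genome-wide expression profiles were available for 2 cultures of THP-1 cells, an established human monocytic acute myeloid leukaemia line. One culture received the solvent DMSO and the other received 2 µM of an agent that the labels name only as OPA1, each for 48 h. OPA1 is here the name of a treatment and not of the mitochondrial gene with the same symbol. The title of the series places the experiment in a study of opioid receptor signalling, TET enzymes and DNA demethylation in leukaemia, so the comparison asks which transcripts differ after exposure to this agent. Each group was 1 library, so no difference below has a replicate check, and no p-value was computed. The values were the authors' FPKM per annotated protein-coding transcript. They covered 29373 transcripts of 11697 gene symbols, and 10601 genes had a mean of at least 1 FPKM after the transcripts of each gene were summed. The listed FPKM values summed to 325059 in the DMSO library and 331515 in the OPA1 library. The number of reads behind them is unknown, so no counting interval can be given.

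The 2 libraries were close to each other. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.97, and the interquartile range of the log2 ratios of OPA1 over DMSO was -0.15 to 0.16. Log2 ratios, medians of lists with their folds, and counts of 2-fold genes below are on the log2(FPKM + 1) scale, which makes differences of low genes smaller. A fold given for a single gene is the plain ratio of its 2 FPKM values and so can exceed 2 in a gene that is not counted as 2-fold. Pairs of FPKM values give the DMSO library first and the OPA1 library second. A total of 209 genes were at least 2-fold higher and 211 at least 2-fold lower in the OPA1 library, together 3.96% of the genes. Such differences were less frequent at high levels, at 6.24% of the genes with a mean of 1 to 2 FPKM and 1.18% of those at 50 FPKM or more.

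Genes that respond to interferon were higher in the OPA1 library. Of 36 measured interferon-stimulated genes, 30 were higher and 6 lower, with a median log2 ratio of 0.29 (1.22-fold). None of 10000 random lists of genes at matched levels had a median as high, and the middle 95% of those lists lay between -0.09 and 0.10. The median was smaller, at 0.157, in the 24 of these genes whose listed transcripts kept steady shares, a restriction chosen after seeing the data. IRF9, the DNA-binding subunit of the interferon-activated factor ISGF3 (chromosome 14, 24630262 to 24635774, hg19), was at 0.83 against 4.94 FPKM (log2 ratio 1.70). PARP9, a partner of the interferon-induced ubiquitin ligase DTX3L, was 2.58-fold higher (2.72 against 7.01 FPKM, log2 ratio 1.11), and MX1, an antiviral GTPase, was 2.35-fold higher (2.37 against 5.57 FPKM, log2 ratio 0.96). DTX3L itself, named after its value was seen, was level at 10.62 against 10.61 FPKM. The higher sums of IRF9 and PARP9 each come from 1 transcript: IRF9-201 was at 0.76 FPKM with DMSO and listed at 0 with OPA1 while IRF9-202 was at 0.07 against 4.94 FPKM, and PARP9-204 was listed at 0 with DMSO and at 5.13 FPKM with OPA1 while PARP9-201 and PARP9-202 were not higher. IFITM1, a membrane protein that restricts virus entry, stood at 17.6 FPKM with DMSO and 32.5 FPKM with OPA1. Other members, chosen after their values were seen, were ISG15, a ubiquitin-like modifier, at 10.6 against 16.9 FPKM, and OAS2, a sensor of double-stranded RNA, at 3.81 against 7.17 FPKM. Of the IFIT family, IFIT1 and IFIT3 were nearly level, at 1.85 against 1.82 FPKM and 2.59 against 2.63 FPKM. The IFITM genes resemble each other in sequence, and reads may have been split between them.

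Genes of antigen presentation were also higher, 16 of 18 measured, with a median log2 ratio of 0.32 (1.25-fold). Again none of 10000 matched random lists had so high a median. NLRC5, a transcriptional activator of MHC class I genes, was 2.34-fold higher (2.08 against 4.87 FPKM, log2 ratio 0.93). B2M, the invariant light chain of MHC class I, was 1.60-fold higher (72.6 against 116 FPKM). HLA-DPA1, a chain of an MHC class II molecule, was at 3.13 against 5.24 FPKM. Lower was CTSS, a lysosomal protease that processes the class II invariant chain, at 42.6 against 24.7 FPKM. HLA genes share sequence with each other and vary between genomes, so the division of reads among them is uncertain.

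Targets of the stress-induced transcription factor ATF4 were lower in the OPA1 library. Of 32 measured genes of the integrated stress response list, 30 were lower, with a median log2 ratio of -0.31, or 1.24-fold lower, and none reached a 2-fold difference. None of 10000 matched random lists had a median as low. PHGDH, the first enzyme of serine synthesis, was 1.95-fold lower (38.5 against 19.7 FPKM). STC2, a secreted glycoprotein induced by stress, was 1.98-fold lower (6.15 against 3.11 FPKM). ALDH1L2, a mitochondrial enzyme of folate metabolism, was 1.75-fold lower (26.2 against 14.97 FPKM), and WARS, the cytosolic tryptophanyl-tRNA synthetase, was 1.5-fold lower (45.7 against 30.5 FPKM). Further members named after their values were seen were PSAT1, of serine synthesis, at 257 against 191 FPKM, and ASNS, asparagine synthetase, at 74.9 against 55.6 FPKM. DDIT3, a transcription factor of the stress response, was at 22.6 against 15.4 FPKM and TRIB3, a pseudokinase, at 40.1 against 28.8 FPKM. The mRNA of ATF4 itself was nearly level, at 288 against 283 FPKM. WARS has a pair of listed transcripts that differ in opposite directions by at least 2-fold.

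**Figure D1:**
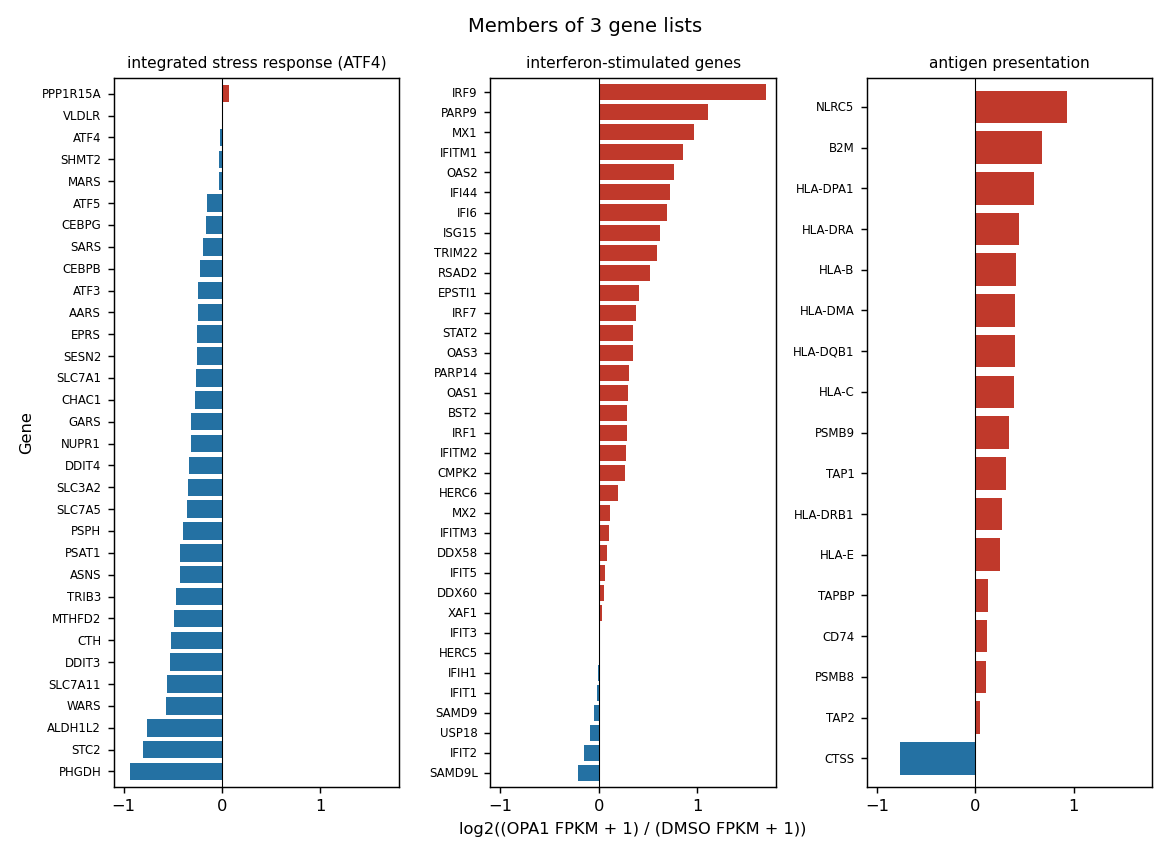
Horizontal bars give log2((OPA1 FPKM + 1)/(DMSO FPKM + 1)) of measured members of 3 gene lists, 1 library per group and no error bars; red bars are higher and blue bars lower in the OPA1 library. Most bars of the ATF4 list point to lower values, with 30 of 32 genes lower, and most bars of the other 2 lists point to higher values.

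The 8 measured genes of the metallothionein and zinc list had a median log2 ratio of -0.29, below all but 21 of 10000 matched random lists, and 7 of them were lower. MT1G was at 13.2 against 8.86 FPKM, MT2A at 36.9 against 26.4 FPKM and MT1X at 54.5 against 40.3 FPKM; these small metal-binding proteins are closely related paralogs, so the division of reads among them is uncertain. SLC30A1, a zinc exporter, was at 9.98 against 7.10 FPKM. Genes of the unfolded protein response were lower in 18 of 25 cases, with a median of -0.08 at percentile 2.46 of the random lists. HYOU1, an endoplasmic reticulum chaperone, was at 73.5 against 44.3 FPKM, XBP1, a transcription factor of this response, at 36.4 against 27.9 FPKM, DNAJB11 at 45.1 against 34.7 FPKM and CANX at 104 against 82.3 FPKM. Nuclear genes of oxidative phosphorylation were higher in 25 of 36 cases, with a median of 0.09 at percentile 98.3. Among them NDUFS1 was at 11.3 against 22.5 FPKM, SDHC at 10.8 against 20.5 FPKM and ATP5D at 23.9 against 30.2 FPKM, while SDHA was lower at 51.3 against 31.6 FPKM. The higher sums of NDUFS1 and SDHC each came mainly from 1 transcript. NDUFS1-209 was at 0.875 against 15.1 FPKM and NDUFS1-201 at 10.4 against 6.09 FPKM. SDHC-201 was at 2.62 against 12.9 FPKM and SDHC-202 at 5.39 against 4.22 FPKM. The lower sum of SDHA came from SDHA-213 alone, at 33.0 FPKM with DMSO and listed at 0 with OPA1. Its other listed transcripts were higher, among them SDHA-201 at 5.28 against 12.4 FPKM and SDHA-204 at 12.7 against 17.8 FPKM. The last 2 lists lay close to the limits set for standing apart, and each lay inside them under 4 alternative settings. The 6 lists named so far are those outside the limits among 31 lists with at least 5 measured genes, where 1.55 would be expected by chance if lists were independent.

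**Figure D2:**
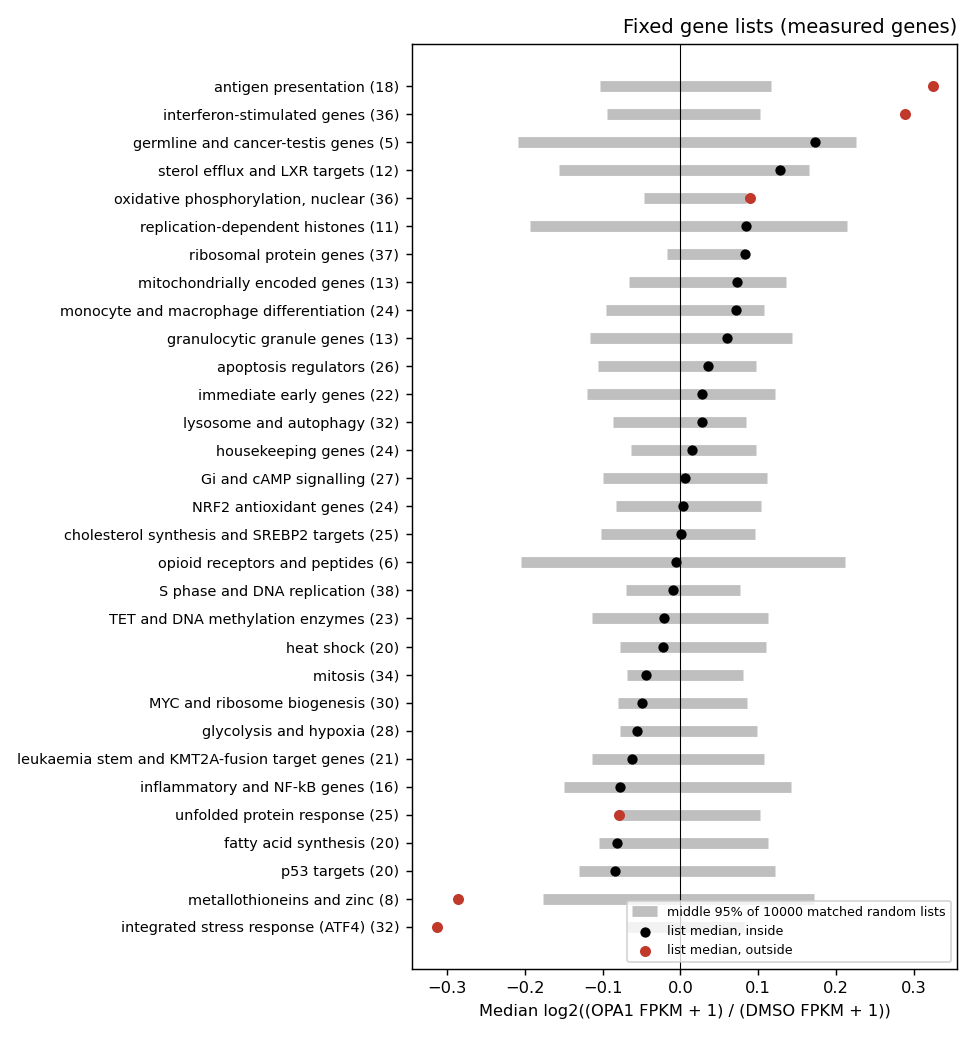
Points give the median log2((OPA1 FPKM + 1)/(DMSO FPKM + 1)) of 31 gene lists, with the number of measured genes in brackets; grey bars span the middle 95% of 10000 random lists matched on size and level, and red points lie outside them. The ATF4 list at -0.31 and the antigen presentation list at 0.32 lie farthest out.

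The list of enzymes of DNA methylation and demethylation lay inside the range of random lists. Of 23 measured genes 10 were higher and 13 lower, with a median log2 ratio of -0.02 at percentile 37.9, and none reached 2-fold. TET2, a dioxygenase that oxidises 5-methylcytosine (chromosome 4, 106067450 to 106200973, hg19, across its listed transcripts), was 1.65-fold higher, at 2.61 against 4.31 FPKM; 13.8% of genes at a like level differed by as much in either direction. TET3 was at 8.38 against 7.54 FPKM and TET1 at 0.60 against 0.57 FPKM. DNMT1, the maintenance methyltransferase (chromosome 19, 10244022 to 10305811), was 1.68-fold lower, at 55.4 against 33.1 FPKM, a difference that 4.91% of genes at a like level matched. The sums of the de novo methyltransferases differed little, with DNMT3A at 3.83 against 3.56 FPKM and DNMT3B at 3.87 against 4.62 FPKM. GADD45B was at 9.53 against 5.27 FPKM and SMUG1, a DNA glycosylase, at 7.19 against 4.14 FPKM. In TET2, DNMT1 and DNMT3B different transcripts carried most of the signal in the 2 libraries. TET2-203 was listed at 2.60 FPKM with DMSO and at 0 with OPA1, and TET2-209 at 0.006 FPKM with DMSO and 3.37 FPKM with OPA1. For DNMT1, transcript DNMT1-202 was at 35.8 against 8.16 FPKM and DNMT1-201 at 4.05 against 24.9 FPKM. For DNMT3B, transcript DNMT3B-202 was at 3.87 against 0.63 FPKM, and DNMT3B-203 was listed at 0 with DMSO and at 3.995 FPKM with OPA1.

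**Figure D3:**
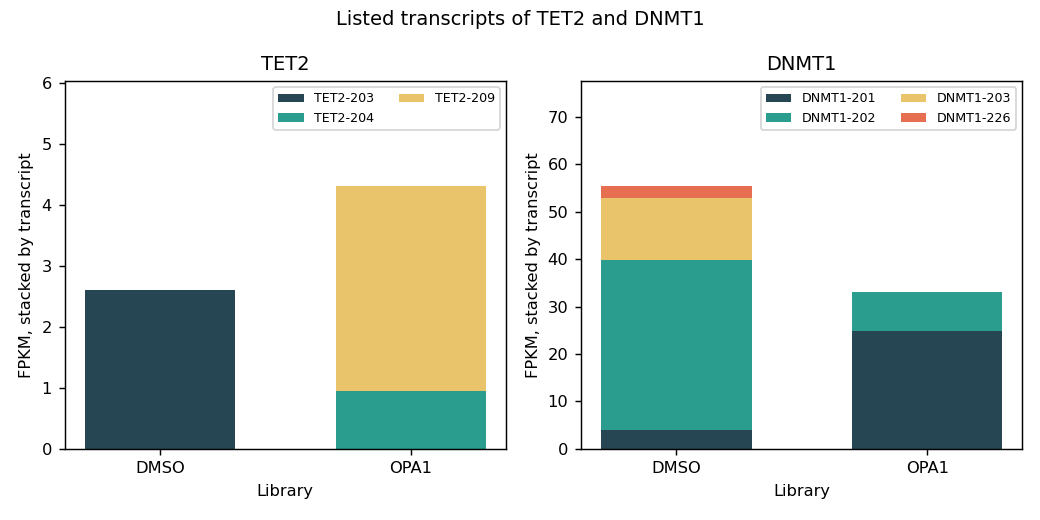
Stacked bars give the FPKM of each listed transcript of TET2 (left) and DNMT1 (right) in the DMSO and OPA1 libraries, 1 library each and no error bars. The TET2 sum was 2.61 FPKM with DMSO and 4.31 FPKM with OPA1, carried by different transcripts, and the DNMT1 sum was 55.4 and 33.1 FPKM.

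For the opioid system, 6 genes had a mean of at least 1 FPKM, with a median log2 ratio of -0.01 at percentile 52.2. Of the receptors, OPRL1, the nociceptin receptor, was listed at 0.72 FPKM with DMSO and 0.90 FPKM with OPA1, and no other opioid receptor gene was analysed here. The 2 OPRL1 values came from different transcripts: OPRL1-201 was at 0.72 against 0 FPKM and OPRL1-202 at 0 against 0.90 FPKM. PNOC, the nociceptin precursor, was at 3.26 against 4.37 FPKM. TMEM97, the sigma-2 receptor, was at 12.2 against 7.29 FPKM, and OGFRL1 was at 32.8 against 28.4 FPKM. In the list of inhibitory G protein and cyclic AMP signalling, 14 of 27 genes were higher and the median was 0.01 at percentile 53.2. GNAI2, an inhibitory G protein subunit, was at 61.3 against 106 FPKM. PRKAR1A, a regulatory subunit of protein kinase A, was at 38.7 against 20.4 FPKM and PRKACA, a catalytic subunit, at 3.62 against 6.64 FPKM. The lower sum of PRKAR1A came mainly from PRKAR1A-214, at 22.6 against 4.81 FPKM. PRKAR1A-221 was lower by less, at 10.6 against 7.55 FPKM, and PRKAR1A-217 was at 3.63 against 4.05 FPKM. CREM, a transcription factor responsive to cyclic AMP, was at 0.06 against 1.98 FPKM.

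Proliferation, death and differentiation lists lay inside the range of random lists. The S phase list had a median log2 ratio of -0.01 over 38 genes (percentile 38.8), with MCM7 at 73.6 against 32.1 FPKM and GINS4 at 26.4 against 11.2 FPKM, both with opposing transcripts, and RFC2 at 30.5 against 43.3 FPKM. The mitosis list had a median of -0.04 over 34 genes (percentile 10.1), and its most divergent gene, FOXM1, was at 12.01 against 9.96 FPKM. The MYC and ribosome biogenesis list had a median of -0.05 (percentile 11.1), with PPAN at 10.2 against 4.28 FPKM and POLR1B at 4.14 against 7.79 FPKM. The p53 target list had a median of -0.08 (percentile 11.0), with FDXR at 2.10 against 3.98 FPKM and TNFRSF10B at 7.22 against 4.41 FPKM. Apoptosis regulators had a median of 0.04 (percentile 78.9), with the protease HTRA2 at 1.09 against 5.34 FPKM and the caspase CASP2 at 13.9 against 1.91 FPKM. Monocyte and macrophage genes had a median of 0.07 over 24 genes (percentile 90.1). Among them the integrin ITGAX was at 2.92 against 6.88 FPKM, the Fc receptor FCGR2A at 11.2 against 19.8 FPKM, C5AR1 at 3.80 against 2.09 FPKM and CD68 at 20.7 against 14.2 FPKM. Granule genes had a median of 0.06 (percentile 77.2), with ELANE, neutrophil elastase, at 363 against 448 FPKM and AZU1 at 702 against 845 FPKM. Leukaemia stem cell and KMT2A-fusion target genes had a median of -0.06 (percentile 15.3), with HOXA7 at 2.25 against 3.42 FPKM and MYB at 32.2 against 27.9 FPKM. The 5 measured germline and cancer-testis genes had a median of 0.17 (percentile 94.9), with MAGEA4 at 2.24 against 3.30 FPKM and MAGEB2 at 60.7 against 68.6 FPKM.

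Metabolic and stress lists gave the following values. The cholesterol synthesis list had a median log2 ratio of 0.00 (percentile 54.2) over members that went both ways: HMGCS1, of the mevalonate pathway, was at 24.0 against 63.1 FPKM, and INSIG1, a sterol sensor, at 63.8 against 27.8 FPKM. Fatty acid synthesis genes had a median of -0.08 (percentile 6.06), with AGPAT2 at 34.5 against 20.1 FPKM and LPIN1 at 2.77 FPKM with DMSO and listed at 0 with OPA1. Sterol efflux genes had a median of 0.13 (percentile 94.1), with PLTP at 9.17 against 12.3 FPKM and NPC2 at 19.9 against 25.2 FPKM. Lysosome and autophagy genes had a median of 0.03 (percentile 77.1), with ATP6V0D1, a proton pump subunit, at 23.7 against 51.8 FPKM and GABARAPL1 listed at 0 with DMSO and at 2.52 FPKM with OPA1. Glycolysis and hypoxia genes had a median of -0.06 (percentile 6.77), with PFKL at 5.38 against 18.0 FPKM, VEGFA at 9.22 against 3.60 FPKM and PKM at 69.8 against 31.1 FPKM. NRF2 genes had a median of 0.00 (percentile 43.6), with NFE2L2, which encodes NRF2, at 10.8 against 38.5 FPKM and TXNRD1 at 37.4 against 19.4 FPKM. Heat shock genes had a median of -0.02 (percentile 20.5), with HSP90AA1 at 528 against 395 FPKM. Inflammatory genes had a median of -0.08 (percentile 15.8), with TNF at 10.7 against 6.29 FPKM and NFKBIA at 12.7 against 19.6 FPKM. Immediate early genes had a median of 0.03 (percentile 70.0), with IER2 at 8.33 against 16.6 FPKM.

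The general composition of the 2 libraries was close. Mitochondrially encoded genes made up 12.8% of the FPKM sum in each, and the median log2 ratio of these 13 genes was 0.07 (percentile 76.9). Ribosomal protein genes had a median of 0.08 (percentile 97.4) and a mean of -0.01, since RPL4 was at 280 against 76.8 FPKM and RPS19 at 603 against 188 FPKM. Replication-dependent histones, whose mRNAs mostly but not always lack a poly(A) tail, had a median of 0.08 (percentile 80.5). Housekeeping genes had a median of 0.01 (percentile 48.3), although TBP was at 21.6 against 9.37 FPKM. Markers of other cell types were too few for a percentile. Of T and NK cell markers 3 had a mean of at least 1 FPKM, among them NKG7 at 26.9 against 27.9 FPKM. There was 1 B cell marker, FCER2 at 1.33 against 1.94 FPKM, and 1 erythroid marker, EPOR at 1.44 against 1.27 FPKM. Of the epithelial and fibroblast markers 4 were measured, including VIM at 214 against 143 FPKM. None of these 9 genes was 2-fold apart.

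The largest single differences involved genes of many functions. Highest in the OPA1 library was KCTD12, an auxiliary subunit of GABA-B receptors (chromosome 13, 77454301 to 77460525, hg19), which was listed at 0 with DMSO and at 10.3 FPKM with OPA1. NUDT4P1, DAG1 and PIK3R2 were likewise listed at 0 with DMSO, and stood at 8.23, 3.93 and 3.86 FPKM with OPA1. WDR75, a ribosome biogenesis factor, was at 0.70 against 16.001 FPKM, LMNB1, a nuclear lamin, at 2.41 against 17.3 FPKM and VPS35, a retromer subunit, at 3.15 against 23.5 FPKM. LPCAT1, an enzyme of phospholipid remodelling, was at 11.4 against 63.7 FPKM, and the splicing kinase CLK1 at 3.29 against 18.8 FPKM. Others of the 15 highest were U2AF1L5 (2.20 against 21.0 FPKM), ZNF267 (0.79 against 10.5 FPKM), TGIF2 (1.19 against 11.3 FPKM), PAXIP1 (1.12 against 9.50 FPKM) and CREB3L2 (1.54 against 10.3 FPKM). U2AF1L5 and NUDT4P1 are near-identical copies of U2AF1 and NUDT4, so their values are uncertain.

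Lowest in the OPA1 library was FP15737, at 12.7 FPKM with DMSO and 0.26 FPKM with OPA1. Of the zinc finger genes, ZNF518A was at 6.72 against 0.03 FPKM, ZNF551 at 7.02 against 0.20 FPKM, ZNF611 at 4.65 against 0.03 FPKM and RBAK at 6.80 against 0.24 FPKM. REV3L, the catalytic subunit of a translesion DNA polymerase, and ANKRD33B were listed at 0 with OPA1, against 5.60 and 4.02 FPKM with DMSO. SELENOF, a selenoprotein of the endoplasmic reticulum, was at 69.7 against 11.9 FPKM, GOLT1B, of Golgi transport, at 23.1 against 3.33 FPKM and MED29, a Mediator subunit, at 16.6 against 1.94 FPKM. The others of the 15 lowest, besides CASP2, were ZDHHC20 (11.0 against 1.02 FPKM), WASHC4 (15.5 against 1.91 FPKM), RINT1 (10.9 against 1.35 FPKM) and RNF130 (15.1 against 2.26 FPKM). Of these 30 genes 2, KCTD12 and NUDT4P1, have a single annotated transcript.

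**Figure D4:**
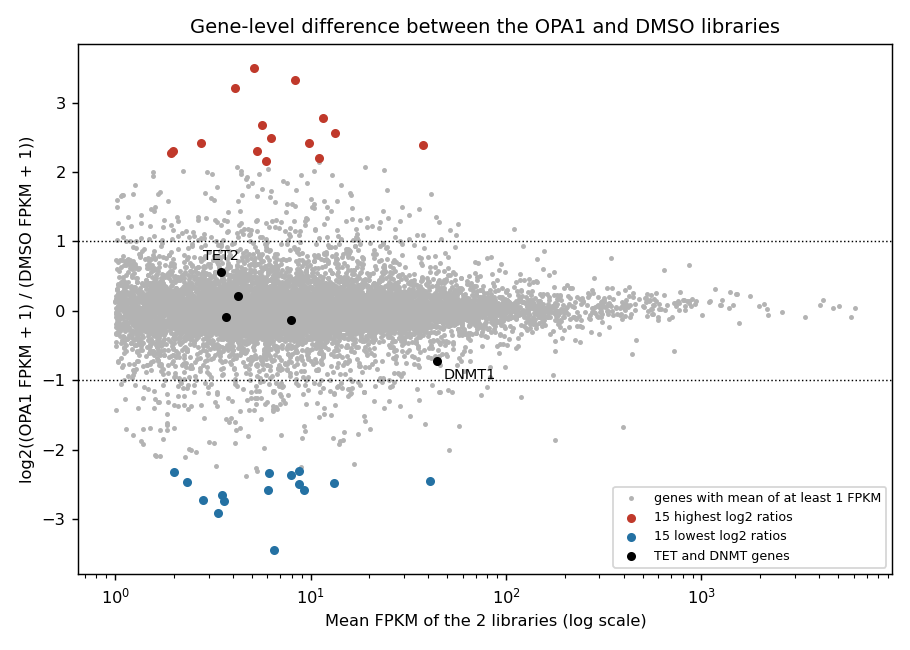
Each point is a gene with a mean of at least 1 FPKM, by mean FPKM of both libraries (x, log scale) and log2((OPA1 FPKM + 1)/(DMSO FPKM + 1)) (y); red and blue mark the 15 highest and 15 lowest ratios, black the TET and DNMT genes, and dotted lines a 2-fold difference. TET2 at 0.56 and DNMT1 at -0.73 lie inside the dotted lines.

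Single transcripts differed far more often than whole genes. Of 19623 transcripts with a mean of at least 1 FPKM, 1783 were at least 2-fold higher and 1789 at least 2-fold lower in the OPA1 library. Among 1517 genes with at least 2 transcripts at a mean of 5 FPKM or more, 222 had a pair going opposite ways by at least 2-fold. The largest exchange was in RPS3A, a ribosomal protein gene, where RPS3A-213 was listed at 0 with DMSO and at 203 FPKM with OPA1, and RPS3A-210 at 480 against 2.11 FPKM. In HDAC2, a histone deacetylase, HDAC2-206 was at 0.006 against 67.7 FPKM and HDAC2-201 at 67.7 against 0.02 FPKM, while the gene's sum was nearly level at 74.4 against 71.7 FPKM. In TARS, the cytosolic threonyl-tRNA synthetase, TARS-201 was at 5.70 against 111 FPKM, and TARS-204 was at 220 FPKM with DMSO and listed at 0 with OPA1. TPT1 was also among the 5 largest exchanges, and TPT1-204 was listed at 0 with DMSO and at 199 FPKM with OPA1. With a minimum of 1 FPKM per transcript, such opposing pairs were also present in TET2, DNMT1, DNMT3B, WARS, MCM7, GINS4, POLR1B, AGPAT2, NFKBIA, SDHA, PKM, TXNRD1, RPS19 and SELENOF.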

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

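With 1 library per group no library can be left out, and the number of reads behind each value is unknown. No paired analysis was possible because each group has 1 library. The count of genes at least 2-fold higher (209) or lower (211) depended on the setting. It was 325 higher and 315 lower with a pseudocount of 0.1 FPKM, 114 higher and 120 lower with a minimum mean of 5 FPKM, and 360 higher and 411 lower after rescaling to 1000000, which makes the fixed pseudocount and minimum weigh less. It was 629 higher and 570 lower with the most abundant transcript per gene. Among the 581 genes with 1 annotated transcript, a restriction chosen after seeing the data, 2 were higher and 3 lower. Among the 6389 genes with steady transcript shares, also chosen after seeing the data, 71 were higher and 60 lower. Transcripts numbered 596 higher and 589 lower with a minimum mean of 5 FPKM, and 3608 higher and 3994 lower after rescaling. The scalings moved the median gene by at most 0.03 (log2). The ATF4, interferon, antigen presentation and metallothionein lists stayed outside the limits under all 11 alternatives in which each had at least 5 genes, with medians of -0.35 to -0.27, 0.16 to 0.34, 0.25 to 0.34 and -0.43 to -0.27. Centring and trimmed-mean scaling shift all genes alike and cannot move a percentile, so they are no check of a list. The metallothionein list lay at percentile 2.48 with the mean, close to the limit of 2.5. The lowest interferon median (0.157, 24 genes) came from the genes with steady transcript shares. The unfolded protein response list moved inside the limits without a filter (-0.079), after rescaling (-0.110), with the mean (-0.119) and after the GC, length and level fit (-0.057). The oxidative phosphorylation list did so with a minimum of 5 FPKM (0.082), the most abundant transcript (0.064), the mean (0.080) and the GC, length and level fit (0.055). Lists that moved outside were fatty acid synthesis with the mean (-0.185), sterol efflux without genes with opposing transcripts (0.163), lysosome and autophagy with the most abundant transcript (0.152), inflammatory genes after the GC, length and level fit (-0.149), and MYC and ribosome biogenesis among genes with steady transcript shares (-0.092). The ribosomal protein list did so without a filter (0.083), after rescaling (0.055) and without genes with opposing transcripts (0.097). The cause was not tested for any of these moves. Of 1085 values of named genes under an alternative, none reversed a 2-fold difference, 1 lost it (ATP6V0D1) and 29 gained it. Of these gains 21 came with the most abundant transcript, including TET2 (0.56 to 2.12) and DNMT1 (-0.73 to -2.01). In both genes that value depends on which of the exchanged transcripts is taken, since another went the opposite way. TET2-203 had a log2 ratio of -1.85 and DNMT1-201 one of 2.36. Most of the 1085 values could not reverse. A minimum mean leaves a gene's ratio unchanged, the pseudocount keeps its sign, and centring and trimmed-mean scaling used shifts of -0.0002 and 0.0001. In practice only the most abundant transcript per gene could reverse a 2-fold difference.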

Other observations

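All tests in this part were chosen after the values of the report were known. Further genes showed the direction of the lists above. Of 26 measured ATF4 targets in none of the lists, 23 were lower in the OPA1 library, with a median log2 ratio of -0.33. JDP2, a repressor of AP-1 sites, was 3.70-fold lower (14.6 against 3.95 FPKM). SLC1A4, a neutral amino acid transporter, was 2.91-fold lower (17.4 against 5.99 FPKM), and CBS, of cysteine synthesis, was 2.13-fold lower (23.9 against 11.2 FPKM). GPT2, a mitochondrial alanine aminotransferase, was at 8.93 against 4.63 FPKM. The mitochondrial aminoacyl-tRNA synthetases, by contrast, had a median of 0.086 over 16 genes (percentile 91.6), which argues against the hypothesis that they are lower like the ATF4 targets; cytosolic synthetases were not tested as a list. This set of comparisons was made within the same 2 libraries and is no replication.

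Members of the antigen presentation list were also split by class, which restates the result of that list and adds no support to it. Class I genes were higher in 10 of 11 cases (median log2 ratio 0.31) and class II genes in 6 of 6 (median 0.40). Outside that list, 31 constitutive proteasome subunits had a median of -0.01 (percentile 26.6). Of 378 ZNF genes 10 (2.65%) were at least 2-fold higher and 14 (3.70%) at least 2-fold lower, against 1.97% and 1.99% of all genes. These shares were not matched on level, with which the 2-fold share varies, and were not tested, so they do not show larger tails. The median of the family, set against lists matched on level, was -0.01 (percentile 32.4) and did not stand apart. Medians by autosome, each set against 2000 matched random lists, lay between -0.04 and 0.04. Of 22 autosomes 5 lay outside the limits used for lists, where 1.1 would be expected by chance: chromosomes 3, 4 and 12 below (percentiles 1.20, 2.05 and 0.40) and 11 and 19 above (percentiles 99.15 and 100). No cause was tested.

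The 420 genes at least 2-fold apart may owe much to how reads were divided among transcripts. Of the 581 genes with 1 annotated transcript, 5 were 2-fold apart where 26.2 were expected from genes of like level with several, a ratio of 0.191 (95% exact interval 0.062 to 0.444). Genes with annotated non-coding transcripts, which the table leaves out, were 2-fold apart 2.570 times as often (interval 1.773 to 3.889) as genes without them at a like number of coding transcripts and like level. Genes with many coding transcripts were pooled into 1 class there and level was matched in broad classes, so differences in transcript number may remain. The intervals of these ratios take the expected number as exact and so are too narrow. Both results are what a division of reads that differs between the libraries would give, and treatment effects on splicing or on longer, more complex genes stay open and untested. TET2 and DNMT1 belong to the 782 genes with opposing transcripts at a mean of at least 1 FPKM, so a reader may want to see the read coverage before using either ratio.

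Higher interferon-stimulated and antigen presentation genes (54 genes together, median log2 ratio 0.294) are a candidate response to OPA1. A trend with GC content, transcript length and level is argued against as the whole cause, since the median was 0.273 after that fit, above every matched random list. Division of reads among the listed transcripts is argued against as the whole cause by the 38 genes with steady transcript shares, in which at most 10% of the FPKM sat on another transcript in the other library: their median was 0.260, above every matched random list. Of these 38 genes 16 have more than 1 listed transcript, and the others meet the limit automatically. The interferon-stimulated genes alone had a smaller median there, 0.157 over 24 genes against 0.288 over 36, so division of reads as a part of the cause stays open for them. Removal of genes with opposing transcripts took out 1 gene and tested nothing, and division with transcripts that the table leaves out was not tested for these lists. A chance choice of genes is argued against, though weakly, by 43 further interferon-stimulated genes, 28 higher and 15 lower. Their median of 0.096 lay at percentile 99.0, close to the upper limit of 0.082 of random lists that treat genes as independent. That median was also smaller and the direction less uniform than in the fixed list. A difference between the 2 cultures other than OPA1 cannot be told apart from the treatment, because there was 1 library per group.

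Lower ATF4 targets (32 genes, median log2 ratio -0.313) are also a candidate response. The median was -0.325 after the fit on GC, length and level, below every matched random list, and the further targets gave -0.334. These values argue against GC or length trends and a chance choice of genes as the whole cause. Division of reads among listed transcripts is argued against as the whole cause by the 25 of 32 genes with steady shares, of which 23 were lower, with a median of -0.310, below every matched random list; 15 of the 25 have more than 1 listed transcript, and the others meet the limit automatically. A rule set before this test was run, that the restriction must take out at least 25% of the genes, was not met and was dropped after the value was seen, because the explanation needs moved shares in the genes that are lower, however many others are taken out. Division with transcripts that the table leaves out was not tested for this list. A difference between the 2 cultures other than OPA1, such as cell density or amino acid supply at harvest, could move the same genes and cannot be told apart from the treatment with 1 library per group.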
